A study of Mus musculus with 2 samples.

How the data were processed

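Messenger and other RNA of sorted spleen CD8+ regulatory T cells was measured in 2 libraries, 1 from WT mice and 1 from Tgfbr2-/-Eomes-/- mice, called DKO. Per the labels' protocols, total RNA was made into libraries with an Illumina TruSeq total RNA kit and sequenced as single-end reads. The labels do not give the number of mice per library, the markers of the sort or how the genes were deleted. Groups were taken from the genotype label.

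The authors deposited whole-number counts of reads per gene for each library, not normalised. The submitters' processing notes name bcl2fastq, TopHat2 2.0.8b, HTSeq and the mm9 genome build without giving their roles or order. Annotation, strand setting and filters are not given in the sources used here. Without a stated strand setting, reads of genes that overlap on opposite strands cannot be told apart. Each deposited file holds 5 rows that name no gene, which were left out of library sizes and ratios. The row of non-unique alignments held 66.4% of the WT rows' total and 64.8% of the DKO rows' total. Reads outside genes made up 4.89% and 4.45%, and ambiguous reads 0.209% and 0.212%. The other 2 of these rows were 0 in both. Gene counts were therefore 28.5% and 30.5% of the totals. Whether a read with several alignments counts once in the non-unique row is not given, so these need not be shares of reads. The 20 most abundant genes held 9.28% and 8.99% of the gene counts. Genes with near-identical copies, such as Ly49, ribosomal protein and Bcl2a1 genes, would lose reads to the non-unique row, and their values are uncertain.

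Counts were scaled by TMM factors from edgeR 4.0.16 in R 4.3.3 (0.983 for WT and 1.02 for DKO) and given as CPM. The log2 ratio used a prior count of 0.5, and each gene's interval is the exact Clopper-Pearson 95% interval of the DKO share of its 2 counts turned into a ratio (scipy 1.17.1). Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. A fold against a library at 0 is taken against a floor of 3 counts in that library (0.137 CPM in WT, 0.150 CPM in DKO). The exact interval of such a gene can start below that fold. Genes with at least 1 CPM in either library were compared, and a gene was counted as higher or lower when its ratio was at least 2-fold and its interval left out 1. A model of variation between animals could not be fitted with 1 library per genotype, so no p-value was computed.

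Before the data were examined, 31 gene lists, the limits and the rule for named genes were fixed. A list's median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and a list was called apart below percentile 2.5 or above 97.5. The 2 targeted genes got no percentile. The percentile describes these libraries. Named genes were Tgfbr2 and Eomes, and the 15 highest and 15 lowest ratios among genes with at least 5 CPM in either library. Intervals of those highest and lowest genes had to leave out 1. Symbols that start with Gm and a digit, LOC, Mir, Snor, Scarna, Rn or ENSMUSG were left out of them. So were symbols that end in Rik, or in -ps or -rs with or without a number. The prefix Rn also leaves out Rnf genes. Also named were up to 4 members per list with the largest absolute log2 ratio at that minimum, and 27 genes whatever their value. Some genes that this rule names are not reported here. Genes outside this rule, given to complete a small count or as a list's largest ratio, in the plot of selected genes and in the closing section, were chosen after their values were seen. Lists overlap: 6 of the 20 measured terminal effector genes, 14 of the 19 identity genes, 4 of the 14 NK markers and 3 of the 11 CD4 and FOXP3 markers were also in another list.

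The reference used here was GRCm38, not mm9, so no coordinates are given; it served for gene neighbours, symbols, and transcript GC content and length, which were found for 11622 of the 11735 genes (99.0%). Spearman correlations of the log2 ratio with GC content and length across genes were -0.02 and -0.06.

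The scripts were tested on simulated data for DKO against WT. With counting error alone, 60% of genes set to a 2-fold difference and 98% of those set to 4-fold were recovered, of 50 genes each, and 24 of 11272 unchanged genes were called. With a coefficient of variation between animals of 0.2, 304 unchanged genes were called, and with 0.4, 2795 of 11316. Of 200 lists of 20 random genes, drawn after log2 ratios were shuffled among genes, 4% without a shift and 99% with a shift of 0.5 were called apart. Shuffling removes any tendency of genes to vary together, so the 4% need not hold for the fixed lists. Alternatives were scaling by total counts or by DESeq2 1.42.0 size factors, no filter or a minimum of 5 CPM, limits of 1.5-fold and 4-fold, a prior count of 5, matching in 10 bins and the mean of a list. Scaling by T cell receptor complex and signalling genes and removal of a GC and length trend (span 0.3) were added after the data were seen.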

Results

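The data came from CD8+ regulatory T cells, CD8+ T cells that restrain other immune cells and are commonly recognised by Ly49 receptors, by CD122 (encoded by Il2rb) and by Helios (encoded by Ikzf2). The cells were sorted by flow cytometry from spleens of unimmunised mice aged 3 months, and the labels do not give the markers used for the sort. One library came from wild-type (WT) mice and 1 from mice labelled as lacking both Tgfbr2, a subunit of the TGF-beta receptor, and Eomes, a T-box transcription factor of effector and memory CD8+ T cells. The library labelled with this genotype is called DKO here. Counts assigned to genes summed to 22307065 in the WT library and 19661212 in the DKO library. Of the 22609 genes listed, 12619 had counts in the WT library and 13284 in the DKO library. The comparison asks how expression in these cells differs when TGF-beta signalling and Eomes are lost together. With 1 library per genotype there was no replicate check and no p-value, and each interval below is an exact 95% interval that covers counting error only. These intervals compare the 2 libraries, not the genotypes.

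Transcripts of both targeted genes, which lie on chromosome 9, were lower in the DKO library, where both were still counted. Eomes had 10292 counts in the WT library and 3589 in the DKO library, or 469 and 180 CPM (counts scaled to library size), which was 2.61-fold lower (interval 2.52 to 2.72). Tgfbr2 had 7825 and 4882 counts, or 357 and 244 CPM, and was 1.46-fold lower (1.41 to 1.51). Both genes lay on the side that the genotype label gives. The counts cover each gene as a whole, so they do not show whether reads came from the deleted part, and a deletion of single exons can leave the rest of the transcript in place. The fixed list labelled as chromosome 9 neighbours of the 2 targets had a median log2 ratio of 0.00. Of its 24 measured genes, 1 was at least 2-fold higher (Fbxl2, 2.00-fold) and 1 at least 2-fold lower (Plcd1, 3.20-fold). Exog and Golga4 in that list were 1.66-fold and 1.52-fold lower, and Slc4a7 was 1.78-fold higher. Chromosomes are given here for the 2 targets only, so a member of the list need not lie near them.

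Differences between the libraries were more often towards higher expression in the DKO library. Among 11735 genes with at least 1 CPM in either library, 1363 were at least 2-fold higher and 422 at least 2-fold lower in the DKO library with an interval that left out a ratio of 1, so 76.4% of these genes were higher. The remaining 9950 genes met neither limit, and the median log2 ratio of the genes was 0.00. This median fell with abundance, taken as the higher CPM of the 2 libraries. It was 0.46 from 1 to 5 CPM, 0.18 from 5 to 20, -0.02 from 20 to 100 and -0.09 at 100 CPM or more. Across genes the 2 libraries had a Spearman correlation of 0.969 (genes are not independent replicates). Among the 2627 genes with at least 100 CPM in either library, 57 were higher and 20 lower. Higher genes at these abundances included Gzma, S100a9 and H2-Aa, and lower ones included Eomes, Gzmm and Cxcr5, as the plot of ratio by abundance shows. With a minimum of 5 CPM in place of 1 CPM, the counts were 739 higher and 146 lower.

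**Figure D1:**
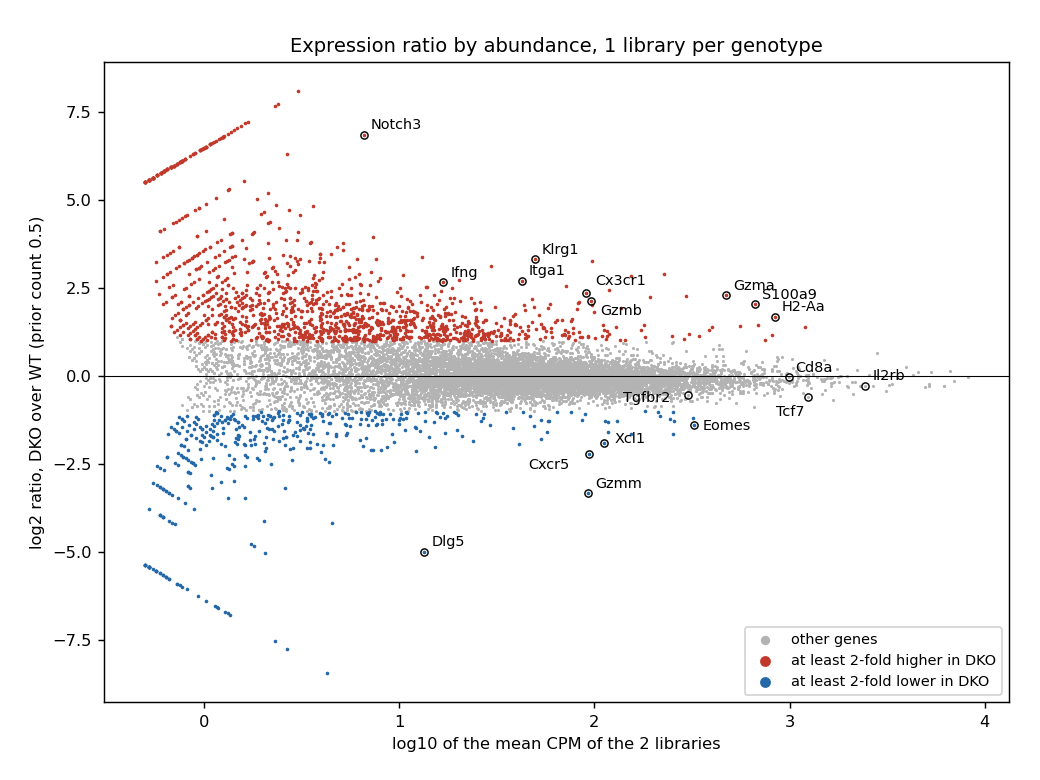
Each point is 1 gene, with the log10 of its mean CPM over the 2 libraries on the horizontal axis and its log2 ratio of DKO over WT on the vertical axis; red and blue points are the 1363 and 422 genes at least 2-fold higher or lower. Straight diagonal rows of points at low abundance are genes with 0 or few counts in 1 library, and the labelled genes were picked from those named in the text.

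Among genes of the cells' identity, the 1 past 2-fold was Cxcr5, the receptor that draws lymphocytes into B cell follicles. Cxcr5 had 155 CPM in the WT library and 33.4 CPM in the DKO library and was 4.66-fold lower (4.29 to 5.07). Of the 19 measured identity genes, Cxcr5 was 1 lower gene, 0 were at least 2-fold higher and 18 met neither limit. Il2rb, at 2675 and 2213 CPM, was 1.21-fold lower (1.19 to 1.22), Ikzf2 was 1.30-fold lower (1.20 to 1.42) and Tox was 1.52-fold lower (1.38 to 1.68). A sort on CD122, if one was used, would set the level of Il2rb and keep NK cells that carry CD122. Cd44 was 1.21-fold higher, Icosl 1.62-fold higher and Tigit 1.61-fold higher. The 2 chains of the CD8 co-receptor, Cd8a and Cd8b1, had log2 ratios of -0.03 and 0.02, and that of Cd8a turned positive when libraries were scaled by total counts or by T cell receptor genes. The median of the list was 0.07, at percentile 95.1 among 10000 random lists of genes of like abundance, which was not apart from them (apart meant outside the middle 95% of them).

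Ly49 receptor genes, whose products mark CD8+ regulatory T cells and NK cells, had a median log2 ratio of 0.51 over 9 measured genes (percentile 95.4, not apart), with 1 at least 2-fold higher, 1 lower and 7 neither. Klra7 was the most abundant of those named, at 227 and 244 CPM, with a log2 ratio of 0.10. Klra9 was 1.52-fold higher, Klra2 1.91-fold higher and Klra8 1.90-fold higher, while Klra17 had 4 and 33 counts, a ratio of 8.17 (4.63 with a prior count of 5), and Klra10, with 113 and 39 counts, was 2.62-fold lower (1.82 to 3.90). Klra6 was listed at 0 in both libraries. These genes are near-identical copies and the counts appear to include only uniquely aligned reads, so their individual values are uncertain. The other NK-type lectin receptors stood apart at a median of 0.72 (percentile 99.96), with 5 of 12 at least 2-fold higher, 0 lower and 7 neither. Klrg1, an inhibitory receptor of terminally differentiated effector cells, had 9.07 CPM in the WT library and 90.1 CPM in the DKO library and was 9.91-fold higher (8.58 to 11.6). Klrb1f was 3.37-fold higher, Klrb1b 2.69-fold, Klrc3 2.87-fold and Klrc2 2.09-fold. NK cell markers were also higher in the DKO library, at a median log2 ratio of 0.98.

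Genes of follicular T cells and follicle homing differed in both directions. Besides Cxcr5, the oxysterol receptor gene Gpr183, which positions cells around follicles, was 1.89-fold lower (1.78 to 2.01). Cd40lg, which encodes the CD4+ T cell ligand that activates B cells, was 6.04-fold higher (4.33 to 8.82) from 39 to 217 counts, and Cd200 had 5 and 119 counts, a ratio of 23.8 (10.9 to 81.9). Of 17 measured genes, 2 were at least 2-fold higher, 1 lower and 14 neither, and the median of 0.18 lay at percentile 96.9, not apart. Markers of CD4+ T cells were higher in the same library, with a median log2 ratio of 1.90. Chemokine receptor genes had a median of -0.01 (percentile 58.0; positive under the same scalings as Cd8a), with 5 of 19 at least 2-fold higher, 2 lower and 12 neither. Cx3cr1, a receptor of circulating effector cells, was 5.15-fold higher (4.73 to 5.61), Xcr1 3.99-fold higher, Ccr9 2.55-fold, Ccrl2 2.44-fold and Ccr1 2.27-fold higher, and Cxcr3 had a log2 ratio of -0.25. Xcr1 is a marker of cross-presenting dendritic cells, and dendritic cell markers as a group had a median of 0.97.

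TGF-beta pathway and Smad target genes, too, were found on both sides, with 4 of 23 at least 2-fold higher, 3 lower and 16 neither, and a median of -0.01 at percentile 53.9 that turned positive under scaling by total counts or T cell receptor genes. Skil, a feedback repressor induced by TGF-beta, was 2.04-fold lower (1.88 to 2.22), and the low-count genes Bambi and Id1, with 74 and 15 and with 64 and 27 counts, were 4.38-fold and 2.14-fold lower. Smad7, an inhibitory Smad induced by the same pathway, was 1.65-fold lower (1.55 to 1.76). Klf11 was 3.13-fold higher (2.62 to 3.79), the co-receptor gene Tgfbr3 2.60-fold, Tgfbi 2.15-fold and Lrrc32, a TGF-beta docking receptor of FOXP3+ T cells, 10.8-fold, from 9 and 93 counts. Tgfbi is also made by myeloid cells, whose markers were higher in the DKO library at a median of 0.89. Itgae, the TGF-beta dependent integrin CD103 of tissue-resident T cells, was low in both libraries, at 14.0 and 18.6 CPM, and 1.33-fold higher (1.14 to 1.55).

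Terminal effector genes were higher in the DKO library and naive and central memory genes were lower. The effector list had a median log2 ratio of 1.45, above each of the random lists, with 15 of 20 genes at least 2-fold higher, 0 lower and 5 neither. Besides Klrg1 and Cx3cr1, S100a4 was 4.72-fold higher (4.46 to 4.99) and Gzma 4.91-fold higher. Prdm1 and Itgam, which are also markers of plasma and myeloid cells, were 2.43-fold and 2.72-fold higher. The T-box gene Tbx21, a paralog of Eomes that drives effector differentiation, had 348 and 382 CPM and a log2 ratio of 0.14. The memory list had a median of -0.38, below each of the random lists, with 1 of 20 genes at least 2-fold higher, 0 lower and 19 neither, and 17 ratios lay below 0. Ccr7, which directs T cells to lymph nodes, was 1.79-fold lower (1.72 to 1.87), and Bach2 was 1.73-fold lower. Tcf7, a transcription factor of stem-like and memory T cells, was 1.5-fold lower (1.47 to 1.53). Dapl1 went the other way and was 2.28-fold higher. Il7r and Bcl2 had log2 ratios of -0.12 and -0.11, both of which turned positive when T cell receptor genes set the scale. NK and myeloid cells also express several of the effector genes, and their markers were higher in the same library, at medians of 0.98 and 0.89.

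Cytotoxic granule and effector cytokine genes were split within the group. Ifng was 6.29-fold higher (5.10 to 7.88) in the DKO library, Gzma, at 160 and 785 CPM, 4.91-fold higher (4.73 to 5.09), and Gzmb, at 35.9 and 157 CPM, 4.38-fold higher (4.05 to 4.75). Gzmm, another granzyme of the same granules, had 168 and 16.7 CPM and was 10.04-fold lower (8.98 to 11.3), and the chemokine gene Xcl1 was 3.70-fold lower (3.45 to 3.98). Prf1, the pore-forming perforin, was 1.22-fold higher. Of 20 genes, 3 were at least 2-fold higher, 2 lower and 15 neither, with a median of 0.34 at percentile 99.99; the mean of the list, 0.25, lay at percentile 95.6 and was not apart. NK cell markers, at 0.98, were higher beside these genes.

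**Figure D2:**
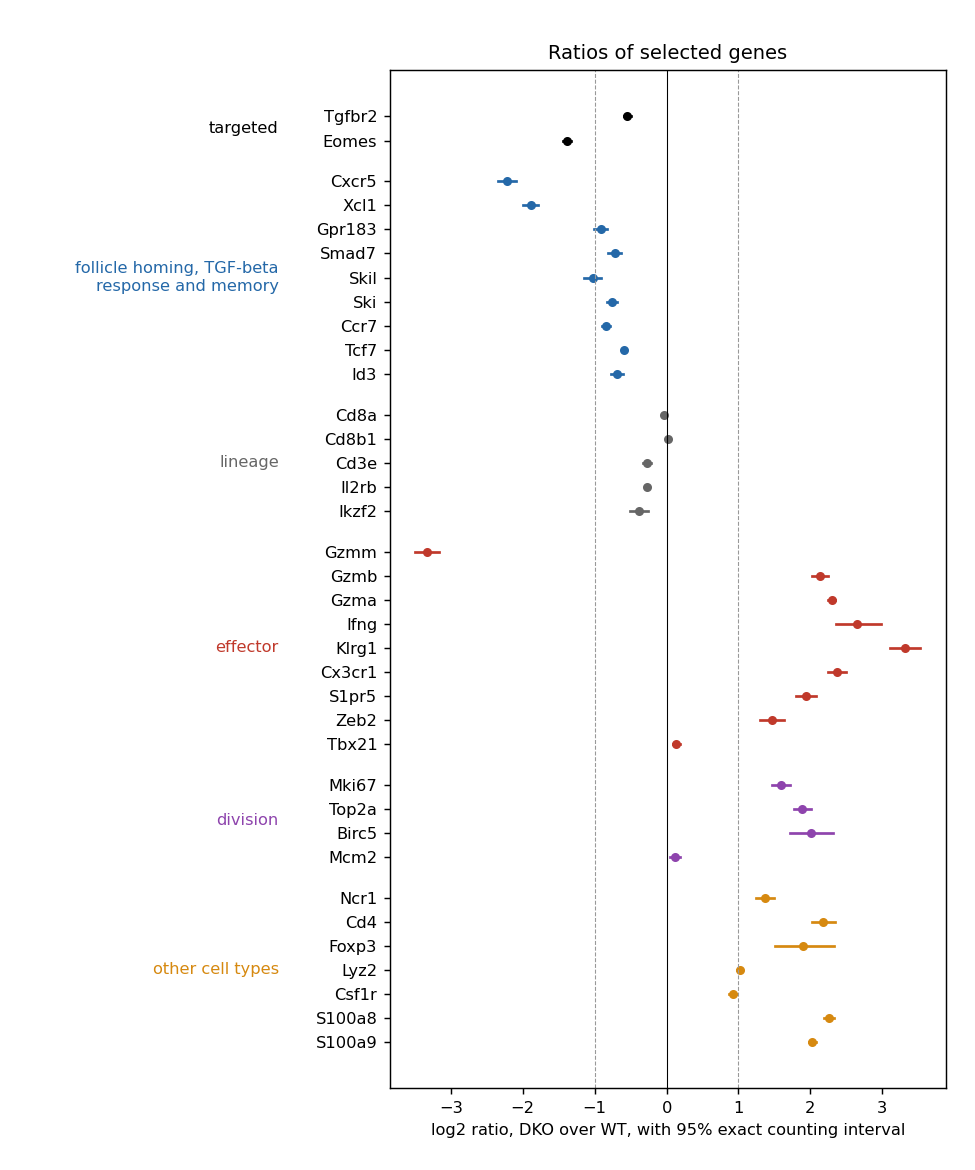
Points are log2 ratios of DKO over WT for single genes, grouped by colour, and bars are exact 95% counting intervals from 1 library per genotype; dashed lines mark a 2-fold difference. The genes were picked from the fixed lists after their values were seen: Gzmm and Cxcr5 lie farthest to the left and Klrg1 farthest to the right, and Cd8a, at -0.03, has the opposite sign under total count or T cell receptor gene scaling.

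Inhibitory receptor and exhaustion genes had a median of 0.51 (percentile 99.7), with 5 of 18 at least 2-fold higher, 1 lower and 12 neither. Ctla4 was 3.82-fold higher (2.82 to 5.33), Lag3 3.27-fold higher (2.67 to 4.04) and Pdcd1 1.44-fold higher (1.14 to 1.82), each below 20 CPM in both libraries. Cd200, Havcr2 (2.66-fold) and Entpd1 (2.20-fold) were the other higher genes, while the nuclear receptor gene Nr4a2 was 3.27-fold lower (2.35 to 4.71). Ctla4 is abundant in FOXP3+ CD4+ T cells, and Foxp3 itself was higher in the DKO library, as given below. Tissue residency and integrin genes stood apart at 0.76, above each of the random lists, with 7 of 19 at least 2-fold higher, 1 lower and 11 neither. Itga1, the collagen-binding integrin CD49a, was 6.51-fold higher (5.70 to 7.5) from 11.3 to 73.5 CPM, Qpct was 5.01-fold and Osgin1 3.24-fold higher, and Xcl1 was the lower gene. Myeloid markers were higher beside both groups, at 0.89.

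Proliferation genes were higher in the DKO library without exception in sign. The median log2 ratio was 1.21, above each of the random lists, and 21 of 36 genes were at least 2-fold higher, 0 lower and 15 neither, with 36 of 36 ratios above 0. Mki67, which encodes the nuclear antigen Ki-67 of cycling cells, had 34.2 and 103 CPM and was 3.00-fold higher (2.76 to 3.27). Tk1 was 6.0-fold higher, the mitotic kinase gene Aurkb 5.26-fold, Ube2c 4.89-fold and Nusap1 4.60-fold. Interferon response genes were also higher, at a median of 0.68, above each of the random lists. It was 0.68 also with the gene listed at 0 in the WT library set at its fold against the floor. Of 30 such genes, 6 were at least 2-fold higher, 0 lower and 24 neither, and 29 ratios lay above 0. Rsad2, an antiviral enzyme, was 3.01-fold higher (2.62 to 3.47), Dhx58 2.29-fold, Oasl2 2.10-fold and Oas1a 2.09-fold. These groups are not specific to a cell type, and the medians of the 8 marker lists of other cell types lay between 0.39 for plasma cells and 1.90 for CD4+ and FOXP3+ T cells.

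T cell receptor complex and signalling genes were slightly lower, at a median log2 ratio of -0.21 (percentile 1.78), with 0 of 24 past 2-fold in either direction and 20 below 0. Nfatc2 was 1.62-fold lower, Vav1 1.46-fold, Zap70 1.38-fold and Fyn 1.36-fold. Ribosomal protein genes had a median of -0.26 (percentile 0.010), with 1 of 48 at least 2-fold lower, 0 higher and 47 neither; Rps28, the lower gene, was 2.16-fold lower, Rpl19 1.72-fold, Rpl13 1.46-fold and Rplp2 1.40-fold lower, and Rpl5 1.73-fold higher. Receptors of gamma-c cytokines and STAT genes had a median of -0.12 (percentile 27.9) and a mean of 0.15 that was apart (percentile 98.5). The median also turned positive when T cell receptor genes set the scale. Of these genes, 2 of 25 were at least 2-fold higher, 0 lower and 23 neither. The higher ones were Il2ra, the alpha chain of the interleukin-2 receptor, at 3.00-fold (2.43 to 3.74), and Il12rb2 at 2.65-fold (2.36 to 2.99). Il18rap and Il10ra were 1.97-fold and 1.64-fold higher. BCL2 family and apoptosis genes had a median of 0.21 (percentile 99.5), with 5 of 24 at least 2-fold higher, 0 lower and 19 neither, namely Bcl2a1b at 3.13-fold, its copies Bcl2a1a and Bcl2a1d at 9.58-fold and 4.67-fold from 7 and 21 WT counts, and Bmf and Pmaip1 each at 2.28-fold; Fas was 1.73-fold higher. Neutrophils and other myeloid cells also express the Bcl2a1 genes, and their markers were higher in the DKO library, at 0.89.

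Immediate early and heat shock genes had a median of 0.12 (percentile 99.4), with 3 of 27 at least 2-fold higher, 1 lower and 23 neither, but their mean of 0.069 lay at percentile 77.3 and was not apart. Atf3 was 2.40-fold higher, Klf4 2.38-fold and Dusp1 2.14-fold, and Hsph1, a heat shock protein gene at 381 CPM in the WT library, was 3.11-fold lower (2.97 to 3.25). Glycolysis genes had a median of 0.01 (percentile 71.6), with 2 of 20 higher, 0 lower and 18 neither; the lactate transporter gene Slc16a3 was 2.96-fold higher, Aldoc 7.87-fold from 11 counts, Slc2a3 1.73-fold and Hk2 1.5-fold higher, and Pfkp 1.52-fold lower. Oxidative phosphorylation genes had a median of 0.04 (percentile 97.57), with 1 of 35 at least 2-fold lower, 0 higher and 34 neither, and a mean of -0.0066 at percentile 59.6. Among them Atp5g1 was 1.64-fold, Ndufb8 1.30-fold and Ndufv1 1.25-fold higher, Uqcrb was 1.31-fold lower and Cycs, the lower gene, 2.76-fold lower. Sex-linked genes had a median of -0.11 (percentile 29.8; positive when T cell receptor genes set the scale) with 0 of 8 past 2-fold, and Y-linked Ddx3y, at 97.7 and 65.9 CPM, and Eif2s3y, at 76.1 and 86.5 CPM, were present in both libraries.

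Markers of cell types other than CD8+ T cells were mostly higher in the DKO library. CD4+ T cell and FOXP3+ regulatory T cell markers had a median log2 ratio of 1.90, above each of the random lists, with 7 of 11 at least 2-fold higher, 0 lower and 4 neither. Cd4 had 17.4 and 79.0 CPM and was 4.53-fold higher (4.05 to 5.08), Foxp3 had 65 and 222 counts and was 3.73-fold higher (2.83 to 5.02), Tnfrsf4 was 7.04-fold and Nrp1 4.19-fold higher. For scale, Cd8a was at 998 and 978 CPM. NK cell markers had a median of 0.98, above each of the random lists, with 7 of 14 higher, 0 lower and 7 neither. Ncr1, a receptor gene of NK cells, had 33.5 and 86.6 CPM and was 2.59-fold higher (2.37 to 2.82), Cma1 was 5.71-fold and Clnk 3.35-fold higher. Macrophage, monocyte and neutrophil markers had a median of 0.89, above each of the random lists, with 9 of 20 higher, 0 lower and 11 neither. The neutrophil calprotectin genes S100a8 and S100a9 were 4.78-fold (4.56 to 5.0) and 4.08-fold (3.96 to 4.2) higher, S100a9 at 1066 CPM in the DKO library, and Lyz1 was 2.85-fold higher. Dendritic cell markers had a median of 0.97, above each of the random lists, with 7 of 14 higher, 0 lower and 7 neither, among them Tcf4 at 3.73-fold and Clec9a at 2.49-fold.

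B cell markers had a median of 0.78 (percentile 99.7), with 8 of 17 at least 2-fold higher, 2 lower and 7 neither, and a mean of 0.74 at percentile 92.2, not apart. Faim3, with 13 and 62 counts, had the largest ratio of the 17 measured genes, 5.08, and the antigen presentation genes H2-Aa, Ciita and H2-Ab1 were 3.21-fold, 3.01-fold and 2.73-fold higher; dendritic cells and macrophages express these genes too. Cd22, an inhibitory lectin of B cells, was 3.44-fold lower (3.11 to 3.81) at 82.8 and 24.1 CPM. Cr2 was the other lower gene, at 2.18-fold. Plasma cell markers were not apart at 0.39 (percentile 91.5), with 2 of 8 higher, 1 lower and 5 neither; Igj, the immunoglobulin joining chain, was 2.06-fold higher, Irf4 1.53-fold and Xbp1 1.26-fold, and Tnfrsf17, with 29 and 10 counts, 2.56-fold lower. Erythroid and platelet markers had a median of 1.31 (percentile 99.9), with 6 of 10 higher, 0 lower and 4 neither, at low counts: Slc4a1 had 26 and 128, Pf4 42 and 138, and Car2 227 and 664. Markers of gamma-delta, NKT and other innate-like T cells were not apart at 0.72 (percentile 83.7), with 1 of 6 higher, 2 lower and 3 neither. Cd163l1, a scavenger receptor gene of gamma-delta T cells, was 3.07-fold lower (2.59 to 3.68), 5830411N06Rik was 2.63-fold lower, Maf was 1.85-fold higher and Zbtb16 was the higher gene, at 2.21-fold. Of the 30 lists with a percentile, 16 lay above the random lists, 3 below and 11 were not apart, where lists of randomly drawn genes would give 1.5 apart. Genes of a list can vary together and lists overlap, so that number does not measure chance differences between animals.

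**Figure D3:**
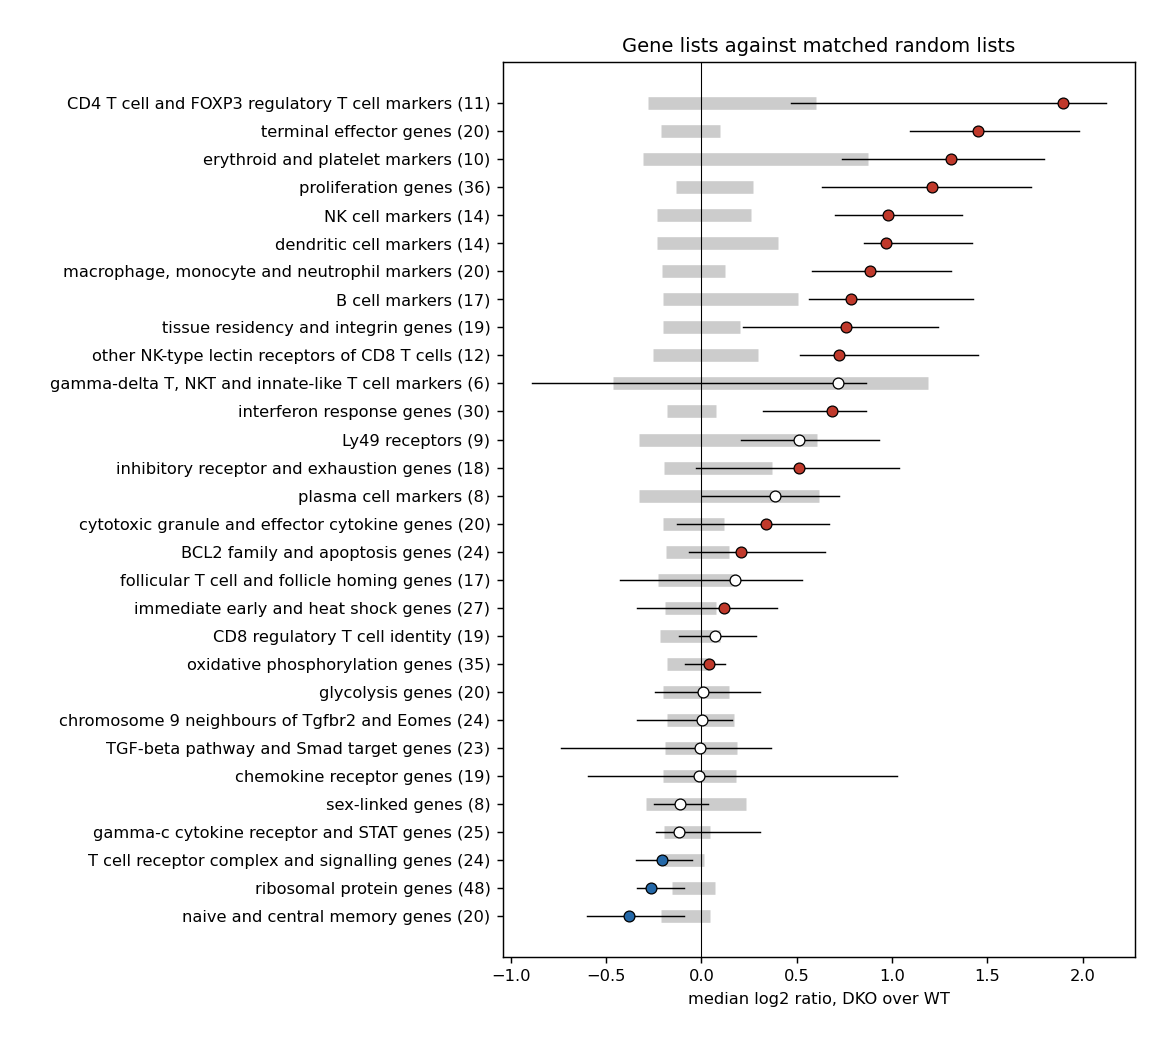
Points are the median log2 ratio of DKO over WT of each fixed gene list, with the number of measured genes in parentheses; thin lines span the quartiles of the members and grey bars the middle 95% of 10000 random lists matched on expression. Red and blue points lie apart above and below the random lists, such as the CD4 and FOXP3 list at 1.90 and the naive and central memory list at -0.38; the medians of the gamma-c and sex-linked lists turn positive when T cell receptor genes set the scale, and those of the TGF-beta and chemokine receptor lists also with total counts.

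Single genes with the largest ratios were mostly of low abundance. The 15 lowest included Lmbr1, Capn11 and Dlg5. Lmbr1, with 188 counts in the WT library and 0 in the DKO library, was 57.1-fold lower against the floor (interval from 46.0 upward). Capn11, with 117 and 0, was 35.5-fold lower against the floor (from 28.5 upward). Dlg5, a scaffold protein gene with 573 and 16 counts, was 31.7-fold lower (19.9 to 57.5). The non-coding RNA gene Kcnq1ot1 was 18.1-fold lower, and Gzmm and Cxcr5 were also in this group. The others, Mapk12, Cmya5, Zfp647, Kcnc1, Hcn3, Phf21b, Lrrc24, Hectd2 and Rmrp, were between 3.97-fold and 5.42-fold lower. The 15 highest included Olfm4, a granule protein gene of neutrophils, with 0 CPM in the WT library and 6.10 CPM in the DKO library. It was 44.6-fold higher against the floor (interval from 35.7 upward). Notch3 had 2 and 262 counts, a ratio of 115 (39.4 to 1193), and Tctex1d2 1 and 106, a ratio of 77.9 (20.4 to 4636). Specc1, Trpm1, Cd200, Itgb2l, Fanca, St5, Alox15, Fam64a, C4b, F10, Map3k12 and Tatdn3 had ratios between 10.9 and 28.2. With a prior count of 5 in place of 0.5, Lmbr1 and Capn11 were 35.2-fold and 22.2-fold lower, and the ratios were 41.8 for Notch3, 27.9 for Olfm4, 20.3 for Tctex1d2, 16.0 for Specc1, 13.6 for Cd200 and 13.5 for Trpm1. In 203 genes 1 library had 0 counts and the other at least 20.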

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

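Reads listed as ambiguous between genes, which lie outside the gene comparison, made up 0.212% of the DKO rows' total (95% Wilson interval 0.210 to 0.213). They made up 0.209% of the WT rows' total (0.208 to 0.210), so the share of all rows was higher in the DKO library. These intervals treat reads as independent and cover counting error only. Both totals consist mostly of the row of non-unique alignments, 64.8% in the DKO library and 66.4% in the WT library. Ambiguous reads numbered 136428 in the DKO library and 163334 in the WT library. With the row of non-unique alignments left out of the totals, their share was higher in the WT library. The order of the libraries therefore depended on that row, and it says nothing about the genotypes. No other explanation was tested.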

How the results depend on the processing

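No paired analysis was possible because each genotype had 1 library, and for the same reason no replicate could be left out. Scaling by T cell receptor genes and removal of the GC and length trend were chosen after seeing the data. The number of higher or lower genes stayed within 1.5 times the reported one in 9 of 16 cases. Without a filter 692 genes were lower, since more genes of low count entered. A minimum of 5 CPM left 739 higher and 146 lower genes, since fewer genes were compared. A 1.5-fold limit gave 2073 higher and 987 lower (67.7% higher), and a 4-fold limit 515 and 138. Scaling by T cell receptor genes moved the median of all genes by 0.21 and put Tgfbr2 at -0.34 and Eomes at -1.18, both still lower, and the counts at 1683 and 321. It turned Cd8a to 0.18, Bcl2 to 0.094 and Il7r to 0.086, and total counts turned Cd8a to 0.019. Of the 195 named genes with counts, these 3 reversed, and 107 further values of named genes left their counting interval, 86 with T cell receptor genes, 16 with total counts and 5 with a prior count of 5. That prior moved 10 named genes by over 1.5 times, each toward 0 and each with at most 5 counts in 1 library. Total counts and DESeq2 size factors moved that median by 0.05 and 0.00.

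Lists kept their side of the limits in 269 of 277 cases, of which 14, in 7 lists that were not apart, changed sign. Another scaling adds the same amount to each gene's log2 ratio, so it could not move a list's percentile. The cases of other scalings therefore bear on the sign of a median only. The mean and the median differed in sign for the identity, TGF-beta, chemokine receptor and chromosome 9 lists. With the mean in place of the median, the cytotoxic list (0.25, percentile 95.6), the immediate early list (0.069, 77.3) and the B cell list (0.74, 92.2) were no longer apart, the oxidative phosphorylation list was -0.0066 (59.6) and no longer apart, and the gamma-c list was 0.15 (98.5), apart and on the other side. The oxidative phosphorylation list was also not apart without a filter (0.041, 97.25) or without the GC and length trend (0.0076, 92.6). The plasma cell list became apart at 5 CPM (0.62, 99.6). The cause of these list differences was not tested. Depth limits the low genes: 3 counts were worth 0.137 CPM in the WT library and 0.150 CPM in the DKO library.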

Other observations

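The gene groups and tests in this part were chosen after the values were seen. Genes of neutrophil granules, some of which are in the myeloid list, had a median log2 ratio of 2.26, with 15 of 19 genes at least 2-fold higher in the DKO library, 0 lower and 19 above 0. Lcn2 was 9.50-fold higher, the immature neutrophil genes Ngp and Ltf 7.49-fold and 7.15-fold, and Camp 5.42-fold. Genes of resident macrophages had a median of 0.65, with 2 of 12 at least 2-fold higher and 10 neither, and C1qa was 1.43-fold higher. Within the proliferation list, 18 of 20 mitotic genes were at least 2-fold higher at a median of 1.63, among them Top2a at 3.70-fold, and the 7 replication licensing and clamp genes had a median of 0.29 (percentile 99.5, apart) with 7 of 7 above 0 and 0 past 2-fold. Within the B cell list, 5 of 5 antigen presentation genes were at least 2-fold higher at a median of 1.45, and the other 12 measured genes had a median of 0.60 (percentile 82.9, not apart) with 3 higher and 2 lower. Lmbr1 and its neighbour Rnf32, with 0 coding genes between them, had 188 and 101 counts in the WT library and 0 in the DKO library.

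Terminal effector genes were higher in the DKO library. Bias from GC content and length is argued against, since their median after removal of that trend was 1.67 over the 17 genes that are in no marker list. More NK cells in the sort predicted a median of these genes at or below the upper quartile of the NK markers, 1.37. The median, 1.62, lay above it. This explanation still stays open, because the lower quartile of these genes, 0.80, lay below 1.37. A larger share of other cells in general stays open too, since the median of 1.62 lay above the upper quartile of the pooled markers of the 8 other cell type lists, 1.45, but the lower quartile did not, and the CD4 and FOXP3 list alone reached an upper quartile of 2.12. A gate on CD8 would remove NK and myeloid cells that lack it, and the labels do not describe the gate.

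Some genes of the fixed lists, outside the cell type markers, were at least 2-fold lower in the DKO library, among them Cxcr5, Gzmm, Hsph1, Klra10, Nr4a2, Skil and Xcl1. Dilution by cells that lack T cell genes as the sole cause is argued against, since it would lower genes specific to T cells at least as far. The lower quartile of the T cell receptor list was -0.34, above the log2 limit of -1. CD4+ T cells share most genes of that list, so it does not bear on dilution by them. Cd8a and Cd8b1, also in the list, had log2 ratios of -0.03 and 0.02. After removal of the GC and length trend the median of 8 such genes, chosen because they were lower, was -1.66, against -1.67 before. The fitted trend therefore accounts for little of the difference in these 8. Eomes, Bambi, Id1, Cycs, Rps28 and Plcd1, also at least 2-fold lower, were not in this set. A larger share of other CD8+ T cells was not excluded. Loss of Tgfbr2 and Eomes is a candidate explanation that cannot be told apart from a difference between animals or sorts, since there was 1 library per genotype.

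Markers of other cell types were higher in the DKO library, but not alike. The medians of the 8 marker lists spanned 1.51, from 0.39 for plasma cells to 1.90 for CD4+ and FOXP3+ T cells. This span lay at percentile 99.4 of those after shuffling members among the lists. It cannot decide on a larger share of other cells that is alike for each type. Markers that CD8+ T cells also express would rise less under such a share, and the lists may hold unlike numbers of them. Larger shares of single types, such as CD4+ T cells or neutrophils, stay open, and Lyz2, abundant in myeloid cells, had 495 CPM in the WT library and 1000 CPM in the DKO library. A difference of the T cells themselves by genotype was untested, as some markers are also expressed by activated CD8+ T cells.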
